A study of Mus musculus with 18 samples.

How the data were processed

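The study measured RNA from pooled cells, sorted for bright EGFP, of MacGreen mice with sterile objects in the peritoneal cavity. Per the labels, there were 18 arrays of 46632 probes in 9 groups of 2, 5 of lavage and 4 of digested capsule cells. Biotin-labelled amplified RNA was hybridised to Illumina mouse bead arrays. The deposited non-normalised file holds, per the file headers, an intensity and a detection p-value for each probe on each array, made with BeadStudio. The intensity is on the linear scale without background subtraction. The p-value compares each probe with negative controls. The deposited series values are log2, quantile normalised by the authors, with BeadStudio and R 2.15.3 named in the submitters' processing notes; their background correction is not given in the sources used here. Across probes, the Spearman correlation of the authors' log2 values and the intensity was 1.00 on each array. Slides were read from the labels: slide 1 held replicate 1 and slide 2 replicate 2 of every lavage group and of capsule day 7, slide 3 held capsule day 14, and slide 4 held capsule day 21 and 28.

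Intensities were background corrected and normalised with neqc in limma 3.58.1 under R 4.3.3, which inferred the controls from the detection p-values, added an offset of 16 and applied quantile normalisation. Probes detected at p 0.05 on both arrays of at least 1 group were kept (20985). Of the probes, 29976 had 1 gene symbol, 10 had several and 16646 had none; the latter 2 kinds were not used for genes. Each gene was read from its kept probe with the highest mean, which gave 10806 genes of the 17711 with a named probe. Csf1r itself had 0 named probes passing and was not analysed here. On any array, 28 probes reached an intensity of 60000, near the top of the scale, where differences are compressed; that of Arg1 (67333) was the only named gene's. Probes of close relatives, such as Rnase2a, Chil4, haemoglobin and Ly6c genes, may share signal, so those genes are uncertain. Psmc1 and Rsl1d1 differed strongly between arrays of 1 group (SD up to 3.17 and 3.86), and sequence variants under their probes were not tested.

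Groups were compared in limma with 1 mean per group over all 18 arrays, 9 residual degrees of freedom and empirical Bayes moderation (prior 4.85), with 2-sided tests, and with Benjamini-Hochberg adjustment within each of 12 comparisons and a threshold of 0.05. Each comparison's genes form 1 family of 10806 tests. Among the comparisons, 5 were set as main: lavage day 2 and day 14 against day 0, capsule day 28 against day 7, and capsule against lavage at day 7 and at day 14. Of 30 gene lists written for this purpose, the 29 with at least 5 measured genes were tested with limma's camera, with a preset correlation of 0.01 and with an estimated one, adjusted over the 29. The lists covered myeloid identity and activation, tissue remodelling, metabolism, cell cycle, dissociation stress and markers of other cell types; lavage day 2 against day 0 gives all 29 by name, and the erythroid list was too small. Of the measured genes, 9 were in more than 1 list, 1 of them in the neutrophil list (Mmp8) and 0 in the dissociation stress list. Macrophages can express members of most of these lists, including Fos and Jun.

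The groups, comparisons, lists, alternatives and the rule for naming genes were set before the data were examined. The rule named, in each main comparison, the 8 largest rises and 8 largest falls among changed genes whose arrays did not overlap between the groups, leaving out names without a gene symbol of their own, with the 3 smallest-p members of each list that passed; the other comparisons named 4 and 4. Other list members given as examples were chosen after their values were seen.

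Labels give slides 1 and 2 to replicates 1 and 2, so replicates of the 6 groups on them shared a slide. Deviations of replicate 1 from its group mean, correlated between those groups over genes, were -0.11 to 0.13 in 15 pairs (median -0.0083; 1 pair above 0.1). The 12 arrays of these slides were fitted with replicate as a block, and values within each slide were taken where both groups were on it. The later capsule groups have no such fit against day 7 or lavage.

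The alternatives were background correction with normexp and an offset of 50, no background correction, median scaling in place of quantiles, the authors' log2 values, no detection filter, a detection p of 0.01, all probes as separate tests, the compared arrays alone, a mean-dependent prior, at least a 2-fold change, the slide as a random block, the replicate block, each array left out in turn, other probes of the named genes and an estimated correlation in camera. Added after the data had been seen were 2 more: only genes detected on all 18 arrays, and the 12 arrays of slides 1 and 2 without the block. No group had at least 3 arrays, so splits of the arrays into other groups were not counted.

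The fits were tested on 20 simulated sets of 10806 genes, 200 of them changed. In lavage day 2 against day 0, genes changed by 0.5, 1 and 2 on the log2 scale were recovered in 9.03%, 74.2% and 99.6% of cases, and 4.56% of calls were false. In the interaction of place and day, 1.42%, 31.8% and 94.1% were recovered, and 5.3% of calls were false. A list shifted by 0.5 was called in all 20 of each, and others 0 times per simulation in the former and 0.05 in the latter. Correlation among list genes was not simulated. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.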

Results

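Transcript levels were measured on mouse bead arrays in cells sorted for bright EGFP from MacGreen mice, a C57Bl/6J reporter line in which the Csf1r promoter drives EGFP in myeloid cells. The cells came from the foreign body response to sterile objects left free in the peritoneal cavity, either from the lavage of the cavity or from the collagenase-digested tissue capsule that formed around the object. There were 18 arrays in 9 groups of 2: lavage cells at day 0 (no implant), 2, 4, 7 and 14, and capsule cells at day 7, 14, 21 and 28. Each array measured RNA from pooled cells, and the labels do not say whether the 2 arrays of a group came from separate animals. The p-values therefore measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision. Mean intensity was 585 to 1053 per array on slides 1 and 2, which carried all lavage arrays and capsule day 7, and 455 to 528 on slides 3 and 4, which carried the later capsule arrays. Between 16442 and 17559 probes per array were detected on slides 1 and 2, and between 18311 and 19345 on slides 3 and 4. Over the 10806 genes tested, the correlation of the 2 arrays of a group was 0.989 to 0.993, and that of arrays from different groups was 0.881 to 0.988. Genes are not independent replicates of these correlations.

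Changes are log2 differences of group means from limma, each with its standard error, and rose or fell is used for genes with an adjusted p under the threshold. For every gene said to have risen or fallen between 2 groups, both arrays of 1 group lay above both arrays of the other. Where no array of a group detected a gene, only a bound is given for a difference of 2 groups, and interaction values of such genes depend on the background. The bound compares the bright group's mean with the dim group's mean of, on each array, the higher of the gene's own value and the lowest signal among detected probes. Gene lists were fixed before the data were examined, and a list is said to be higher or lower where limma's camera passed with the preset correlation. A gene or list that did not reach the threshold is said to have failed. The adjusted p of a list is given with the preset correlation and then with the correlation estimated. Values without either array of a group are for replicate 1 left out and then replicate 2. Of 103 list results that passed, 82 failed with an estimated correlation, and for 96 of the 103 that value was the highest adjusted p of any alternative tried.

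**Figure D1:**
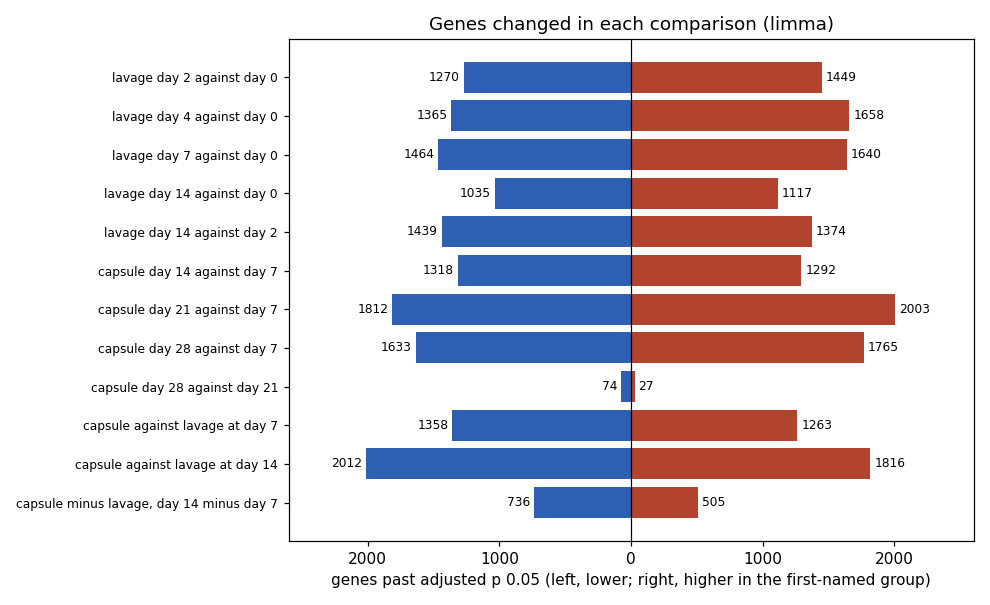
Number of genes higher (right) and lower (left) at an adjusted p under 0.05 in each of the 12 comparisons, out of 10806 tested. Bars for capsule day 28 against day 21 are the shortest (27 higher, 74 lower), and those for capsule against lavage at day 14 hold 1816 higher and 2012 lower genes; with median scaling the higher share fell to 13.8% in lavage day 14 against day 0 and 12.6% in lavage day 14 against day 2.

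The comparison of lavage day 2 with day 0 asked how cells of the cavity changed in the early inflammatory phase after implantation. In total 2719 genes changed, 1449 higher and 1270 lower. S100a9, an alarmin abundant in neutrophils and inflammatory monocytes, rose from 5.65 ± 0.21 to 14.41 ± 0.39 (normalised log2 intensity, SD, n = 2 arrays per group), a change of 8.76 (SE 0.49, adjusted p 2.61e-08), although only 1 of the 2 day 0 arrays detected it. Its change was 8.89 within slide 1 and 8.64 within slide 2. S100a8 rose by 5.27 (SE 0.24, adjusted p 6.47e-09) and the cytokine gene Il1b by 6.51 (SE 0.26, adjusted p 2.78e-09). The chemokine receptor gene Cxcr2 was at least 23.9-fold higher, the iron exporter gene Slc40a1 at least 37.4-fold, Entpd3 at least 38.0-fold and Wfdc21 at least 44.3-fold, and Gcnt2 rose by 5.20. The neutrophil marker list was higher, with 7 of 11 measured members past the threshold (7 adjusted over the list alone) and a median change of 2.33 (adjusted p 4.46e-06; 0.119 estimated). Neutrophils of MacGreen mice can carry the reporter as well. The classical monocyte list was also higher, with 4 of 7 members up and Mgst1 down by -1.85 (list alone, the same counts). The median was 1.08 (adjusted p 0.0457, 0.197 estimated). Ccr2, the chemokine receptor of recruited monocytes, rose by 3.18 and S100a4 by 1.08.

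Genes that mark resident peritoneal macrophages fell over the same 2 days. Of 15 measured members, 12 were lower (12 adjusted over the list alone), with a median of -2.47 (adjusted p 2.72e-11; 0.119 when estimated; -3.16 within slide 1 and -2.50 within slide 2). Gata6, the transcription factor of large resident macrophages, went from 13.14 ± 0.08 to 9.96 ± 0.78 (SD, n = 2 arrays per group), a change of -3.17 (SE 0.27, adjusted p 1.13e-06). Alox15 changed by -5.20 and Tgfb2 by -4.99. The B cell chemokine gene Cxcl13 had the largest fall of any gene, -5.53 (SE 0.38, adjusted p 1.98e-07), and Apoc1 changed by -5.12. Wnt2, Fscn1 and Rad51b each changed by between -4.98 and -4.99, and Lama3 by -4.81, detected on 1 of 2 day 2 arrays. A second named probe of Lama3 did not fall (0.44, adjusted p 0.332). Complement genes were lower in 4 of 7 members (4 list alone) and higher in 1 (2 list alone), with Cfb at -3.12, C1qa at -2.16 and C1qc at -1.58. The median was -1.20 (adjusted p 0.0182, 0.197 estimated).

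Further lists were higher at day 2. In the matrix protease list 6 of 13 members rose and 1 fell (8 and 2 list alone), with Timp1 at 4.66, Mmp14 at 4.10 and Mmp12 at 3.04 (day 0 detected on 1 of 2 arrays). The median was 0.73, or 0.62 with undetected members at their bound (adjusted p 0.00194, 0.119 estimated). Glycolysis and hypoxia genes rose in 9 of 15 members (9 up and 1 down list alone), led by Ndrg1 at 2.89, Ankrd37 at 2.50 and Slc2a1 at 1.88. The median was 0.56 (adjusted p 0.00051, 0.119 estimated). Alternative activation genes rose in 6 of 14 members and 1 fell (7 and 1 list alone), with Arg1 at 2.71, Chil4 at 3.13 and Tgm2 at 3.04. The median was 0.38 (adjusted p 0.00209, 0.18 estimated). Giant cell and osteoclast genes rose in 5 of 12 members and 1 fell (same list alone), with Ctsk at least 7.91-fold higher, Gpnmb at 2.99 and Trem2 at 1.97. The median was 0.48, or 0.25 with bounds (adjusted p 0.0249, 0.197 estimated). Inflammatory cytokine and enzyme genes rose in 5 of 12 members and 1 fell (same list alone), with Il1rn at 3.13 and Tnf at 1.73, both detected on 1 of 2 day 0 arrays. The median was 0.25 (adjusted p 0.0397, 0.368 estimated). Dissociation stress genes rose in 7 of 14 members (8 list alone), with Fos at 2.32, Jun at 1.91 and Zfp36 at 1.22. The median was 0.83, or 0.67 with bounds (adjusted p 0.00051, 0.18 estimated).

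B cell, eosinophil and mast cell and cell cycle genes were lower at day 2. B cell markers fell in 7 of 8 members (8 list alone), with Blk at -1.95, Pou2af1 at -1.39 and Blnk at -0.90. The median was -1.20 (adjusted p 7.66e-05, 0.134 estimated). Eosinophil and mast cell markers fell in 4 of 8 (4 list alone), with Mcpt4 at -1.67, Cpa3 at -1.62 and Cma1 at -1.43. The median was -0.71, or -0.60 with bounds (adjusted p 0.0177, 0.119 estimated). Cell cycle genes fell in 3 of 14 (4 list alone), namely Cdc20 at -1.20, Cdk1 at -0.98 and Birc5 at -0.92. The median was -0.32 (adjusted p 0.0351, 0.38 estimated). The lists that failed included myeloid identity (adjusted p 0.136), class II antigen presentation (0.482), chemokine (0.0711), interferon response (0.894), lysosome (0.189), lipid handling (0.846), scavenger and efferocytosis (0.288), matrix (0.489) and smooth muscle and myofibroblast (0.844). Growth factor (0.441), oxidative phosphorylation (0.364), iron and heme (0.851), T and NK cell (0.305), dendritic cell (0.489), mesothelial (0.261) and endothelial markers (0.846) did not pass either. The median and mean of the interferon response and of the iron and heme lists, or the direction of their test, differed in sign.

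The classical monocyte list failed without lavage day 0 replicate 2 (adjusted p 0.081) or without lavage day 2 replicate 2 (0.0506), and the cell cycle list failed without the same arrays (0.0518 and 0.0664). The giant cell list (0.0506) and Cdk1 (0.0763) failed without lavage day 2 replicate 2, and Birc5 without lavage day 0 replicate 2 (0.0518). Without lavage day 2 replicate 1 the count of changed genes was 1777. The inflammatory list failed with the authors' values (0.0521), an offset of 50 (0.078), no background correction (0.0823), the compared arrays alone (0.163), the 12 arrays of slides 1 and 2 with the replicate block (0.0786) or without it (0.0686), or genes detected on all arrays (0.404). With the latter the giant cell list (median 1.00, adjusted p 0.195) and the classical monocyte list (0.0756) did not pass either. The inflammatory median was 0.15 without lavage day 2 replicate 1 and 0.42 without replicate 2, and the giant cell median 0.93 without lavage day 0 replicate 2. The monocyte list failed with the authors' values (0.0564) or a detection p of 0.01 (0.0554), the eosinophil and mast cell list (0.0521) and Cpa3 (0.0513) with the authors' values, and the cell cycle list with the slide as a random block (0.101). Of other named probes, 1 of 2 for Gcnt2 and for Chil4, 2 of 3 for Gpnmb and all for Tgm2, Blnk, Birc5 and Cdc20 failed (adjusted p 0.106 to 0.97), and 1 for Gpnmb had a change of -0.02. The other probes of the first 3 gave 1.11, 3.19 and 1.67 and passed.

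At lavage day 4, compared with day 0 to follow the cavity into the next phase, 3023 genes changed, 1658 higher and 1365 lower. S100a9 was still raised at 8.60 (SE 0.49, adjusted p 4.42e-08), and the macrophage elastase gene Mmp12 rose by 7.07 (SE 0.24, adjusted p 2.87e-10), each detected on 1 of 2 day 0 arrays. Gpnmb rose by 6.70 and the monocyte chemokine gene Ccl7 by 5.81. Apoc1 changed by -4.40, Lama3 by -4.27, Foxq1 by -4.06 and Cxcl13 by -3.88; a second probe of Lama3 did not fall (0.18, adjusted p 0.717). Cell cycle genes were higher in 13 of 14 members (13 list alone), with Top2a at 2.10 and Cdk1 at 2.18. The median was 1.39 (adjusted p 2.41e-08, 0.0794 estimated). Alternative activation genes rose in 12 of 14 members (12 list alone), among them Chil4 at 4.01, Tgm2 at 3.65 and Arg1 at 3.17. The median was 1.55 (adjusted p 4.58e-09, 0.0496 estimated). Within slides 1 and 2 that median was 1.57 on each.

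Chemokine genes rose in 11 of 16 members and fell in 2 at day 4 (11 and 3 list alone), with Ccl2 at 5.09 and Ccl12 at 4.75. The median was 1.59 (adjusted p 0.000546, 0.285 estimated). Giant cell and osteoclast genes rose in 8 of 12 and fell in 2 (same list alone). The median was 1.54, or 1.24 with bounds (adjusted p 0.000546, 0.0915 estimated). Matrix protease genes rose in 8 of 13 and fell in 1. The median was 1.00 (adjusted p 9.02e-05, 0.0496 estimated). Neutrophil markers (7 of 11 up, median 1.48, adjusted p 9.02e-05, 0.145 estimated) and dissociation stress genes (9 of 14 up, median 0.83, adjusted p 0.000184, 0.145 estimated) remained higher than at day 0. Glycolysis and hypoxia genes (7 of 15 up, median 0.74, adjusted p 0.000283, 0.0915 estimated) and growth factor genes (5 of 10 up, median 0.67, adjusted p 0.0296, 0.171 estimated) were also higher. Resident macrophage genes were lower in 8 of 15 (10 list alone, median -1.09, adjusted p 6.69e-05, 0.226 estimated), B cell markers in 5 of 8 (7 list alone, median -1.19, adjusted p 0.000283, 0.145 estimated) and eosinophil and mast cell markers in 4 of 8, with 1 higher (median -1.12, adjusted p 0.000897, 0.0496 estimated). With genes detected on all arrays the chemokine (median 0.77, adjusted p 0.127), giant cell (1.05, 0.06) and growth factor lists (0.26, 0.469) failed. Without lavage day 0 replicate 1 the growth factor median was 0.44, and without replicate 2 the glycolysis median was 0.37. Among the 17 lists that failed, the signs of median, mean and test differed for scavenger, iron and heme, T and NK cell and mesothelial genes. With median scaling the median of all genes moved to 0.14 and 69.6% of the changed genes were higher, against 54.8% here, and without lavage day 0 replicate 2 the count was 1933.

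Lavage day 7 against day 0 addressed the cavity once a capsule had formed, and 3104 genes changed, 1640 higher and 1464 lower. Rnase2a, an eosinophil-type ribonuclease gene, rose by 8.05 (SE 0.17, adjusted p 9.75e-13; 7.95 within slide 1 and 8.15 within slide 2); its close relatives share sequence, so the probe may not separate them. Its intensity reached 56224 on a scale with a highest value of 71532, where differences may be compressed. Gpnmb rose by 6.85, the protease gene Ctsk was at least 59.4-fold higher and Wfdc21 at least 79.5-fold. Cxcl13 changed by -8.30 (SE 0.38, adjusted p 2.99e-09), Apoc1 by -7.22 and the scavenger receptor gene Marco by -5.89, and Lama3 was at least 30.01-fold lower. The other probe of Lama3 (adjusted p 0.878) and 1 of 3 of Gpnmb (0.124) failed, while the others of Gpnmb gave 5.90 and 4.48. Alternative activation genes rose in 12 of 14 members (12 list alone), with Chil4 at 5.26, Pdcd1lg2 at 4.45 and Mgl2 at 3.86. The median was 1.97 (adjusted p 9.12e-11, 0.0404 estimated). Cell cycle genes rose in 13 of 14 (13 list alone). The median was 1.91 (adjusted p 7.31e-10, 0.0786 estimated). Oxidative phosphorylation genes rose in 11 of 15 (12 list alone, median 0.71, adjusted p 0.000326, 0.0786 estimated) and glycolysis and hypoxia genes in 9 of 15 (11 list alone, median 0.83, adjusted p 0.00016, 0.0786 estimated).

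Matrix protease genes at day 7 rose in 8 of 13 members and fell in 1 (8 and 2 list alone). The median was 0.83 (adjusted p 0.00102, 0.0786 estimated). Of the resident macrophage genes 9 of 15 were lower and 1 higher (10 and 1 list alone), the exception being Lyve1 at 3.32. The median was -1.16 (adjusted p 3.9e-05, 0.256 estimated). B cell markers were lower in 5 of 8 (5 list alone). The median was -1.01 (adjusted p 0.00328, 0.256 estimated). S100a9 was still 3.26 above day 0, while the neutrophil list as a whole failed (adjusted p 0.129). Lists whose median, mean and test differed in sign, none of which passed, were myeloid identity, inflammatory cytokine, smooth muscle, growth factor, iron and heme and mesothelial. Without lavage day 0 replicate 2 the count was 2045.

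By lavage day 14, compared with day 0 to ask how far the cavity had returned to its resting state, 2152 genes still differed, 1117 higher and 1035 lower. Rnase2a remained raised, from 7.35 ± 0.11 to 15.52 ± 0.06 (SD, n = 2 arrays per group), the latter high on the scale as at day 7, a change of 8.17 (SE 0.17, adjusted p 7.96e-13; 8.05 and 8.29 within slides 1 and 2). The C-type lectin gene Clec4g rose by 7.44 (SE 0.31, adjusted p 1.63e-09) and Ucp1, the uncoupling protein gene of brown fat, by 6.02 (SE 0.37, adjusted p 4.67e-08). Fxyd6 was at least 64.5-fold higher, Wfdc21 at least 57.5-fold and Mall at least 30.5-fold, and Gpnmb rose by 5.84. Among falls, Marco changed by -6.74 (SE 0.55, adjusted p 7.84e-07), Apoc1 by -6.59, Dmpk by -6.37, Cxcl13 by -5.98 and Fscn1 by -5.25. The haemoglobin genes Hba-a1 (-5.20, detected on 1 of 2 day 14 arrays) and Hbb-bt (-4.80) also fell; they belong to the erythroid list, of which 4 of 8 genes were measured, too few to test. Chil1 changed by -4.79 (SE 1.36, adjusted p 0.0229), but only 1 of 2 day 14 arrays detected it and the change was -8.27 within slide 1 and -1.31 within slide 2. It failed without lavage day 14 replicate 1 (-1.38, adjusted p 0.113; -8.20 without replicate 2), or either lavage day 0 array (0.0973 and 0.095), with the authors' values (0.0502) or with the compared arrays alone (0.122).

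Resident macrophage genes at day 14 failed as a list (2 of 15 higher, 5 lower, 2 and 6 list alone, median -0.56, adjusted p 0.215). Gata6 stood at 13.34, against 13.14 at day 0, a change of 0.20 that did not pass. Timd4 and Vsig4 were lower by -2.18 and -2.33, and Tgfb2 by -1.79, whereas Lyve1 was higher by 3.22. Alternative activation genes were higher in 9 of 14 members (11 list alone), with Chil4 at 5.40, Tgm2 at 3.49 and Arg1 at 3.16. The median was 1.23 (1.09 and 1.27 within slides 1 and 2), with adjusted p 4.57e-09, and 0.0349 when estimated. Glycolysis and hypoxia genes were higher in 7 of 15 (8 list alone), with Ankrd37 at 2.44, Slc2a1 at 2.07 and Ndrg1 at 1.41. The median was 0.48, or 0.45 with bounds (adjusted p 5.84e-05, 0.0848 estimated). Oxidative phosphorylation genes were higher in 9 of 15 and lower in 1 (12 and 1 list alone), with Sdhc at 0.94, Uqcrc1 at 0.74 and Ndufa4 at -0.96. The median was 0.54 (adjusted p 0.001, 0.137 estimated). In the matrix protease list 5 of 13 rose and 2 fell (same list alone), with Timp1 at 5.80, Mmp12 at 5.48 (1 of 2 day 0 arrays) and Mmp14 at 2.89. The median was 0.44, or 0.25 without lavage day 0 replicate 1, with adjusted p 0.0338, and 0.256 when estimated, 0.0652 with the replicate block, 0.0533 with the same 12 arrays without it and 0.339 with genes detected on all arrays.

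Eosinophil and mast cell markers were lower in 5 of 8 members and higher in 1 at day 14 (same list alone), with Cpa3 at -3.96 and Cma1 at -2.50, each detected on 1 of 2 day 14 arrays, and Mcpt4 at least 6.09-fold lower. The median was -1.42, or -1.10 with bounds (adjusted p 0.000458, 0.0349 estimated). B cell markers were lower in 4 of 8 (5 list alone), with Blk at -1.78, Pou2af1 at -1.62 and Cd79a at -1.47. The median was -1.16 (adjusted p 0.001, 0.256 estimated), or -0.68 without lavage day 14 replicate 2, when Cd79a changed by -0.84. Interferon response genes were lower in 2 of 9 (4 lower and 1 higher list alone). The median was -0.67 (adjusted p 0.0338, 0.568 estimated), or -1.04 without lavage day 0 replicate 1. The list failed with the replicate block (0.0598), the same 12 arrays without it (0.0533), the slide as a random block (0.0821), median scaling (0.241), no detection filter (0.0505) or a detection p of 0.01 (0.156). Rsad2 changed by -2.22 and Mx1 was at least 1.91-fold lower, while Irf7 at -1.38 failed (adjusted p 0.0559). The interferon list failed without lavage day 0 replicate 2 (adjusted p 0.146), or either lavage day 14 array (0.054 and 0.072), and Rsad2 failed without lavage day 0 replicate 2 (0.0627). The neutrophil list failed (median 0.06, adjusted p 0.809), with S100a9 at 8.02 (5.65 at day 0). Median, mean and test differed in sign for the chemokine, lysosome, iron and heme, mesothelial and endothelial lists, which failed. The other probe of Tgm2 (adjusted p 0.645), 1 of 3 of Gpnmb (0.309) and 1 of 4 of Hbb-bt (0.152) did not pass, and the remaining ones of Gpnmb (4.55 and 3.03) and Hbb-bt (-4.79 to -5.29) did. With median scaling the median of all genes moved to -0.29, 3553 genes changed and 13.8% of these were higher, against 51.9% here. The count was 1406 without lavage day 0 replicate 1 and 1296 without lavage day 0 replicate 2.

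Lavage day 14 was also set against lavage day 2, to separate the late cavity from the early phase, and 2813 genes differed, 1374 higher and 1439 lower. Clec4g was higher by 8.45, Rnase2a by 8.24, Ucp1 by 8.22 and the arginine transporter gene Slc7a2 by 6.79 (SE 0.23, adjusted p 3.64e-10); 1 of 2 day 2 arrays detected Clec4g and Ucp1. S100a9 changed by -6.39 (SE 0.49, adjusted p 5.61e-07) and Il1b by -6.16, and Fcgr1, the high-affinity Fc receptor gene, was at least 39.7-fold lower and Slc40a1 at least 33.7-fold lower. Resident macrophage genes were higher in 11 of 15 members (11 up and 1 down list alone). The median was 1.95 (2.73 and 1.29 within slides 1 and 2), with adjusted p 4.29e-07, and 0.238 when estimated. Neutrophil markers were lower in 8 of 11 (8 list alone). The median was -2.75 (adjusted p 4.29e-07, 0.238 estimated). Dissociation stress genes were lower in 7 of 14 (9 list alone, median -0.82, or -0.68 with bounds, adjusted p 0.000695, 0.238 estimated) and chemokine genes in 8 of 16, with 2 higher (9 and 2 list alone, median -1.16, or -0.89 with bounds, adjusted p 0.00454, 0.487 estimated). The chemokine median was -0.53 without lavage day 2 replicate 1 and -0.76 without lavage day 14 replicate 1.

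Between the same days, alternative activation genes were higher in 7 of 14 and lower in 1 (8 and 1 list alone). The median was 0.45 (adjusted p 0.00454, 0.238 estimated). Classical monocyte genes were lower in 5 of 7 and higher in 1 (median -1.13, adjusted p 0.00827, 0.238 estimated), and cell cycle genes were higher in 5 of 14 and lower in 1 (median 0.48, adjusted p 0.0156, 0.463 estimated). Myeloid identity genes were lower in 5 of 11 and failed without lavage day 2 replicate 2 (0.0646) or with genes detected on all arrays (0.151). The median was -0.42 (adjusted p 0.0237, 0.238 estimated), or -0.24 without lavage day 14 replicate 1. Oxidative phosphorylation genes were higher in 5 of 15. The median was 0.33, with adjusted p 0.0393, and 0.324 when estimated, 0.0501 with the replicate block, 0.125 with the slide as a random block and 0.0564 with genes detected on all arrays. That list failed without lavage day 2 replicate 1 (0.0683), or either lavage day 14 array (0.0538 and 0.066). Eosinophil and mast cell markers were lower in 5 of 8, and the list failed without lavage day 2 replicate 2 (0.0776) or lavage day 14 replicate 2 (0.0696). The median was -0.87, or -0.78 with bounds, with adjusted p 0.0406, and 0.238 when estimated, 0.0541 with the replicate block and 0.0612 with those 12 arrays without it. This list did not pass with an offset of 50 (0.0567), no background correction (0.0609) or no detection filter (0.161) either. Interferon response genes were lower in 4 of 9, and the list failed without lavage day 2 replicate 1 (median -0.10, adjusted p 0.442; -1.76 without replicate 2), or either lavage day 14 array (0.0625 and 0.0947). The median was -0.96, or -0.32 with bounds, with adjusted p 0.0462, and 0.574 when estimated, 0.0632 with the replicate block, 0.0612 with those arrays without it, 0.125 with the slide as a random block, 0.0813 without a detection filter and 0.141 with a detection p of 0.01. Giant cell, glycolysis and iron lists, which failed, had medians, means and tests that differed in sign. With median scaling the median of all genes moved to -0.38 and 12.6% of 4955 changed genes were higher, against 48.8% here, and the chemokine, myeloid identity, classical monocyte, interferon, cell cycle, oxidative phosphorylation and eosinophil and mast cell lists failed (0.0614 to 0.381).

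**Figure D2:**
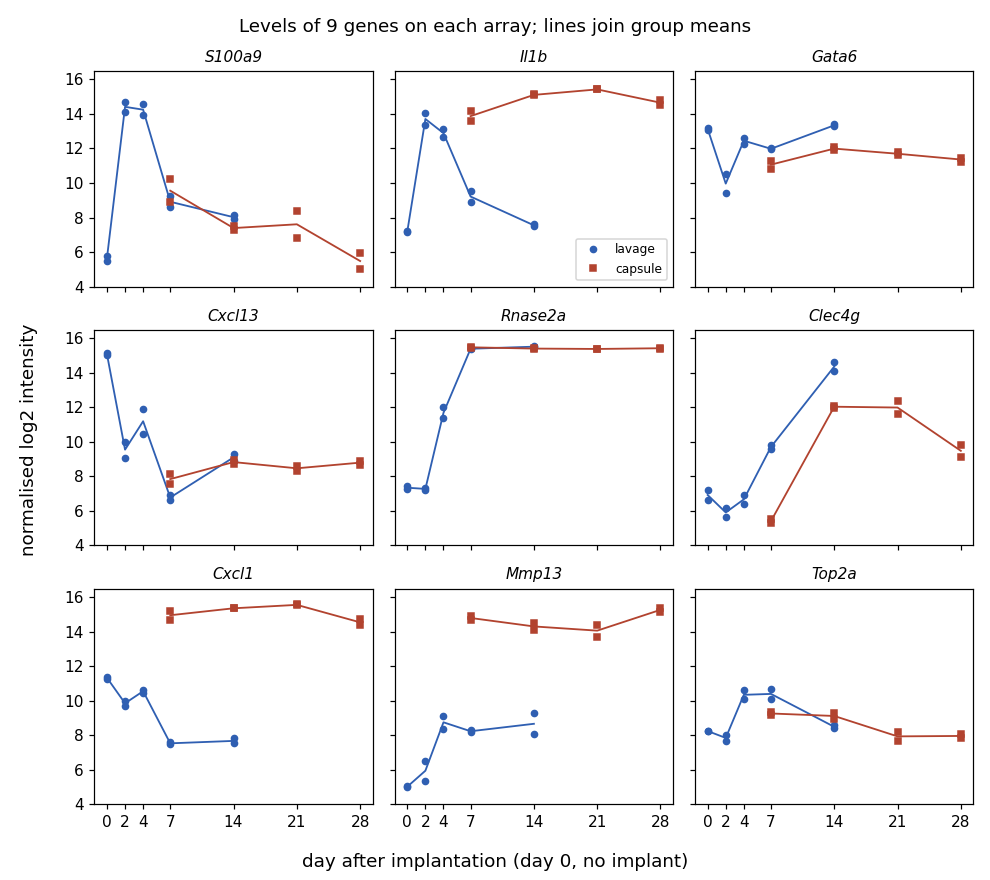
Normalised log2 intensity of 9 genes against day after implantation, with 1 point per array (circles, lavage; squares, capsule) and lines through the means of 2 arrays. S100a9 in lavage goes from 5.65 at day 0 to 14.41 at day 2, Gata6 from 13.14 to 9.96 and back to 13.34 at day 14, and Cxcl1 lies at 14.96 in capsule and 7.54 in lavage cells at day 7.

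Capsule and lavage cells of day 7 were compared to ask how myeloid cells in the tissue differ from those free in the cavity, and these 4 arrays lay on slides 1 and 2, each slide holding 1 array of either kind. In all 2621 genes differed, 1263 higher and 1358 lower in capsule cells. The neutrophil-attracting chemokine gene Cxcl1 was at 14.96 ± 0.36 in capsule and 7.54 ± 0.09 in lavage cells (SD, n = 2 arrays per group), a difference of 7.42 (SE 0.18, adjusted p 9.49e-12; 7.74 within slide 1 and 7.10 within slide 2). Cxcl2 was higher by 7.00 (SE 0.25, adjusted p 3.83e-10) and Tnf at least 101.8-fold higher. The collagenase gene Mmp13 was higher by 6.56, Ch25h by 6.46, the cell fusion gene Ocstamp by 6.02 and the immediate early gene Fosb by 5.69, and F3, the tissue factor gene, was at least 36.1-fold higher. Clec4g was at least 16.46-fold lower in capsule cells, Cd79a at least 10.0-fold, Cpa3 at least 10.8-fold and Pou2af1 at least 5.63-fold. Cldn10 (-3.58), Sult1a1 (-3.39), Vmn2r26 (-3.36) and Fxyd6 (-3.22) were lower as well, while of 4 other probes of Cldn10, 2 gave -3.74 and -3.58 and passed and 2 gave 0.01 (adjusted p 0.983) and -0.13 (0.728).

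Inflammatory cytokine and enzyme genes were higher in capsule cells in 10 of 12 members (11 list alone). The median was 3.90, or 3.73 with bounds (4.08 and 3.66 within slides 1 and 2), with adjusted p 1.77e-15, and 0.0062 when estimated. Nfkbiz at 3.73 and Tnfaip3 at 4.29 were higher too. Chemokine genes were higher in 13 of 16 (13 list alone), with Cxcl16 at 2.00 and Ccl24 at 0.99. The median was 2.21, or 2.00 with bounds (adjusted p 8.98e-11, 0.0558 estimated). Giant cell and osteoclast genes were higher in 11 of 12 and lower in 1 (same list alone), with Ctsk at 2.605 and Dcstamp at least 10.1-fold higher. The median was 1.53 (1.30 and 2.01 within slides), with adjusted p 1.83e-08, and 0.0062 when estimated. Matrix protease genes were higher in 11 of 13 and lower in 1, with Mmp14 at 3.43 and Plau at 2.36. The median was 1.78 (adjusted p 9.18e-10, 0.0062 estimated). Matrix genes were higher in 6 of 9 (7 list alone), with Lox at least 26.4-fold, Col4a2 at least 1.51-fold and Dcn at 2.26, detected on 1 of 2 lavage arrays. The median was 0.94, or 0.58 without capsule day 7 replicate 1, or 0.60 with bounds (adjusted p 0.000365, 0.0704 estimated). Growth factor genes were higher in 7 of 10 (8 list alone), with Vegfa at 3.56, Hbegf at 2.92 and Pdgfb at 1.81. The median was 1.24 (adjusted p 4.14e-06, 0.00806 estimated). Glycolysis and hypoxia genes were higher in 11 of 15, with Ndrg1 at 3.70, Slc2a1 at 2.51 and Adm at least 8.11-fold. The median was 1.35 (adjusted p 1.12e-09, 0.0062 estimated). Lipid handling genes were higher in 7 of 14 and lower in 1 (10 and 1 list alone), with Lpl at 2.39 and Fabp5 at 2.25. The median was 0.98, or 0.94 with bounds (adjusted p 2e-05, 0.0062 estimated).

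Dissociation stress genes, listed because collagenase digestion can induce them, were higher in capsule cells in 12 of 14 members (12 list alone), with Fos at 3.13, Ier3 at 2.92 and Zfp36 at 2.40. The median was 2.42, or 2.30 with bounds (adjusted p 1.4e-12, 0.00747 estimated). Alternative activation genes were higher in 7 of 14, with Clec7a at 2.11 and Tgm2 at 1.66. The median was 0.56, or 0.37 with bounds (adjusted p 0.00256, 0.131 estimated). Cell cycle genes were lower in 12 of 14 (12 list alone), with Cdc20 at -1.78, Mcm7 at -1.52 and Mcm5 at -1.48. The median was -1.08 (adjusted p 4.68e-06, 0.0804 estimated). Resident macrophage genes were lower in 8 of 15 (8 down and 1 up list alone), with Garnl3 at -2.27, Icam2 at -2.00 and F5 at -1.94. The median was -0.71 (adjusted p 0.00155, 0.323 estimated). Eosinophil and mast cell markers were lower in 5 of 8 (6 list alone), with Cma1 at least 3.76-fold and Mcpt4 at least 3.16-fold lower. The median was -1.22, or -0.87 with bounds (adjusted p 1.75e-05, 0.0062 estimated). Class II antigen presentation genes were lower in 5 of 11 (7 down and 1 up list alone), with Ciita at -1.30, H2-Eb1 at -0.92 and H2-DMb1 at -0.75. The median was -0.49 (adjusted p 0.0157, 0.161 estimated). Oxidative phosphorylation genes were lower in 4 of 15, with Uqcrc1 at -0.66, Cox5a at -0.49 and Ndufa1 at -0.40. The median was -0.34 (adjusted p 0.00989, 0.131 estimated). B cell markers were lower in 4 of 8 and higher in 2, Blnk among the latter at 1.87. The median was -1.03 (adjusted p 0.0396, 0.323 estimated). Neutrophil (0.331), T and NK cell (0.281), mesothelial (0.261) and smooth muscle lists (0.0683) did not pass, and the iron and heme list, which failed, had a median and mean that differed in sign.

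H2-DMb1 did not pass without lavage day 7 replicate 2 (0.16), without capsule day 7 replicate 2 (-0.45, adjusted p 0.213) or with the replicate block (0.0505), nor did Ciita without the same arrays (0.0877, and 0.0827 at -0.83). Cox5a failed without either lavage day 7 array (0.0719 and 0.119) or capsule day 7 replicate 2 (0.169). Ndufa1 failed without lavage day 7 replicate 1 (0.184), either capsule day 7 array (0.114 and 0.0933) or with the block (0.0619), as did Ccl24 (0.0643) and Col4a2 (0.0686) without capsule day 7 replicate 1. The oxidative phosphorylation (0.0543) and B cell lists (0.0638) did not pass without lavage day 7 replicate 1, nor the class II list without capsule day 7 replicate 2 (median -0.30, 0.0732). Without lavage day 7 replicate 2 the count was 1701. With the compared arrays alone Ndufa1, Cox5a, H2-DMb1 and Ciita failed (0.0559 to 0.128), as did Ndufa1 (0.0563), Cox5a (0.0595) and the class II (0.0623), oxidative phosphorylation (0.0855) and B cell lists (0.0654) with median scaling, or the B cell list with an offset of 50 (0.0628) or no background correction (0.0688). The other probes of Hbegf, Pdgfb, Tgm2 and Ciita and 1 of 3 of Dcn failed (adjusted p 0.109 to 0.854), and the remaining ones of Dcn gave 1.27 and 1.29. The median of all genes moved to -0.20 with median scaling, and 27.04% of the changed genes were higher, against 48.2% here.

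The same contrast at day 14 gave 3828 genes, 1816 higher and 2012 lower in capsule cells, and here the slide and the group cannot be told apart, since the capsule arrays lay on slide 3 alone. Cxcl1 was higher by 7.68 (SE 0.18, adjusted p 5.89e-12), Il1b by 7.55 (SE 0.26, adjusted p 1.45e-10) and Cxcl2 by 7.26, and Tnf was at least 90.1-fold and Ccl12 at least 67.4-fold higher. Fosb was higher by 7.38, detected on 1 of 2 lavage arrays, Ch25h by 6.99 and Rgs1 by 6.11. Eif2s3y, a gene of the Y chromosome, was at least 18.5-fold and Gfi1b at least 10.00-fold lower. Alox15 (-3.63), Glul (-3.63), Cd79a (-3.59), Cd79b (-3.40) and Wfdc21 (-3.17) were also lower. Rsl1d1 changed by -3.36 (SE 1.05, adjusted p 0.0225) but was detected on 1 of 2 capsule arrays, and it failed without either lavage day 14 array (0.073 and 0.0936), with the authors' values (0.0517) or with the compared arrays alone (0.124). Its change was -0.63 without capsule day 14 replicate 1 and -6.09 without replicate 2.

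Inflammatory cytokine and enzyme genes were higher in 11 of 12 members at day 14 (11 list alone), with Nfkbiz at 4.17. The median was 3.82 (adjusted p 3.08e-12, 0.0133 estimated). Dissociation stress genes were higher in 13 of 14 (13 list alone), with Ier3 at 3.70 and Zfp36 at 3.02. The median was 2.97 (adjusted p 1.1e-11, 0.0133 estimated). Chemokine genes were higher in 11 of 16 (12 list alone). The median was 3.83, or 3.57 with bounds (adjusted p 3.45e-09, 0.074 estimated). Matrix protease genes were higher in 11 of 13 (11 list alone), with Mmp13 at 5.64, Plau at 3.64 and Mmp14 at 2.98. The median was 2.31 (adjusted p 3.02e-08, 0.0133 estimated). Matrix genes were higher in 8 of 9 (9 list alone), with Dcn at least 27.2-fold, Lox at least 18.6-fold and Col6a1 at least 4.78-fold. The median was 1.71, or 0.96 with bounds (adjusted p 5.49e-06, 0.0311 estimated). Growth factor genes were higher in 9 of 10 (9 list alone), with Hbegf at 5.34, Vegfa at 4.52 and Osm at 3.49. The median was 1.27 (adjusted p 2.55e-06, 0.0133 estimated). Glycolysis and hypoxia genes were higher in 13 of 15 (13 list alone), with Adm at least 16.8-fold, Ndrg1 at 3.28 and Pfkp at 1.59. The median was 1.30 (adjusted p 9.88e-09, 0.0133 estimated). Giant cell and osteoclast genes were higher in 8 of 12, with Gpnmb at 2.51, Trem2 at 2.24 and Dcstamp at least 3.18-fold. The median was 2.25, or 1.95 with bounds (adjusted p 5.64e-06, 0.0213 estimated).

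Alternative activation genes at day 14 were higher in 8 of 14 and lower in 1, with Ccl17 at least 4.38-fold, Pdcd1lg2 at 2.34 and Tgm2 at 1.38. The median was 0.58, or 0.53 with bounds (adjusted p 0.00288, 0.16 estimated). Lipid handling genes were higher in 6 of 14, with Scd2 at 1.24 and Lpl at 1.18; without lavage day 14 replicate 1 the list failed (0.0754). The median was 0.42 without lavage day 14 replicate 2 and 0.22 and 0.33 without either capsule day 14 array. With all arrays it was 0.14 (adjusted p 0.0284, 0.074 estimated). Oxidative phosphorylation genes were lower in 7 of 15 (7 list alone), with Cox7b at -1.70, Ndufb5 at -1.63 and Atp5a1 at -2.02, although a second probe of Atp5a1 gave 0.02 (adjusted p 0.969). The median was -0.40 (adjusted p 0.00138, 0.074 estimated). The resident macrophage list was lower, with 7 of 15 members down and 1 up (8 and 1 list alone), among them Tgfb2 at -2.92 and Timd4 at -1.40. The median was -0.87 (adjusted p 0.0132, 0.556 estimated). B cell markers were lower in 4 of 8 and higher in 1, with Pou2af1 at least 5.39-fold lower, and the list failed without lavage day 14 replicate 1 (0.0929) or capsule day 14 replicate 1 (0.0522), with an offset of 50 (0.0529), no background correction (0.0557) or the authors' values (0.0502). The median was -1.07 (adjusted p 0.0409, 0.483 estimated). The neutrophil list did not pass, with 0 of 11 members changed (median -0.05, adjusted p 0.965), nor did the T and NK cell list (0.965) or the mesothelial list (0.546). Myeloid identity, complement, neutrophil, T and NK cell, dendritic and endothelial lists had medians, means and tests that differed in sign. Of 3 other probes of Dcn 1 did not pass (0.599).

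**Figure D3:**
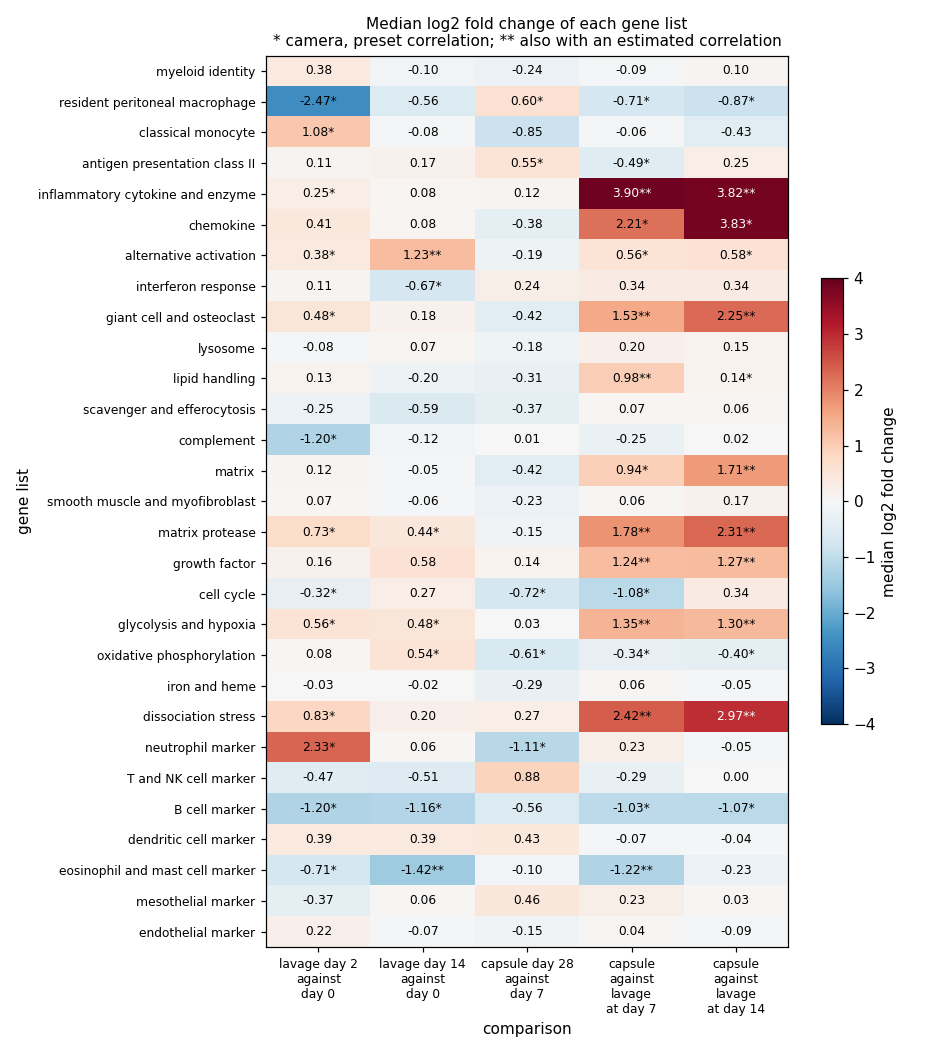
Median log2 change of 29 gene lists (vertical axis) in the 5 main comparisons (horizontal axis), with colour for the median, 1 star for lists past camera with the preset correlation and 2 stars for lists that also passed with an estimated correlation. Inflammatory cytokine genes lie at 3.90 and 3.82 in capsule against lavage at day 7 and 14, and resident macrophage genes at -2.47 in lavage day 2 against day 0.

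Whether the difference between capsule and lavage cells itself changed from day 7 to day 14 was tested as an interaction, and 1241 genes differed, 505 higher and 736 lower. Ccl12 rose in capsule relative to lavage by 4.44 (adjusted p 0.000922) and Gas6 by 3.28 (adjusted p 0.000331), while Fzd1 changed by -4.19 (adjusted p 5.52e-05), Zfp661 by -3.04 and Glul by -2.97. Neither lavage day 14 array detected Ccl12, no capsule day 14 array detected Cpa3 (3.16) or Eif2s3y (-5.87) and 1 of 2 detected Fzd1, and no capsule day 7 array detected Psmc1, so the sizes of these depend on the background. Psmc1 at 5.87 (SE 1.68, adjusted p 0.0367) did not pass without lavage day 7 replicate 1 (3.63, adjusted p 0.127), lavage day 14 replicate 1 (0.127) or any 1 of the 4 capsule arrays (0.0815 to 0.0858), nor with the authors' values (0.0971) or no detection filter (0.0715). Cell cycle genes were higher in 9 of 14 members and lower in 1 (10 and 1 list alone, median 1.48, adjusted p 7.75e-06, 0.34 estimated), as were eosinophil and mast cell markers in 4 of 8 (4 list alone, median 1.22, adjusted p 0.000726, 0.0674 estimated). MHC class II genes were higher in 5 of 11 (6 up and 2 down list alone), and the list failed without capsule day 7 replicate 2 (median 0.48, 0.0846). The median was 0.74 (adjusted p 0.0314, 0.552 estimated). Matrix genes were higher in 2 of 9, and the list failed without lavage day 7 replicate 1 (0.0841), lavage day 14 replicate 1 (0.173), capsule day 7 replicate 2 (0.157) or capsule day 14 replicate 2 (median 0.29, 0.254). The median was 0.71 (adjusted p 0.0439, 0.552 estimated). Dissociation stress genes were higher in 2 of 14, and the list failed without lavage day 7 replicate 1 (0.0836), lavage day 14 replicate 1 (0.174), capsule day 7 replicate 2 (0.145) or capsule day 14 replicate 1 (0.1). The median was 0.63 (adjusted p 0.0439, 0.623 estimated). The class II, matrix and dissociation stress lists did not pass with median scaling (0.107, 0.387 and 0.107) or the compared arrays alone (0.0548, 0.0548 and 0.0552) either. The matrix list had a median of 0.036 without a detection filter (0.547) and failed with the authors' values (0.0566) or a detection p of 0.01 (0.07). Dissociation stress did not pass with the authors' values (0.107) or the slide as a random block (0.0683), nor did it (0.0587) or class II (0.0587) with genes detected on all arrays. Among lists that failed, alternative activation, interferon, lysosome, complement, glycolysis, oxidative phosphorylation, iron and dendritic lists differed in sign between median, mean and test. The median of all genes moved to 0.29 with median scaling, and 74.2% of the changed genes were higher, against 40.7% here. The count was 824 without lavage day 14 replicate 1, 811 without lavage day 7 replicate 2, 805 without capsule day 7 replicate 2 and 768 without capsule day 14 replicate 2.

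In the capsule, the later days were compared with day 7 to follow cells as the capsule matured; day 7 lay on slides 1 and 2 and the later days on slides 3 and 4, so for these 3 comparisons the slide and the group cannot be told apart. From day 7 to day 28 there were 3398 genes changed, 1765 higher and 1633 lower. Cdkn2a, a cell cycle inhibitor gene, rose by 4.57 (SE 0.38, adjusted p 4.05e-06), the resident macrophage gene Tgfb2 by 3.65, the muscle-type oxidase subunit gene Cox6a2 by 3.60, Pcolce2 and Adcy4 by 3.16 each and Slc10a6 by 2.97. Clec4g was at least 14.1-fold and Psmc1 at least 17.1-fold higher. Wfdc21 changed by -5.17 (SE 0.60, adjusted p 4.44e-05; 1 of 2 day 28 arrays), Csta2 by -5.03, S100a9 by -4.07 (1 of 2), Eno2 by -3.53, Mmp9 by -3.46 and Mt3 by -3.40 (1 of 2), and Zfp979 was at least 7.00-fold lower. Chil1 changed by -4.83 (adjusted p 0.0159; 1 of 2 day 28 arrays) but failed without either capsule day 7 array (0.0779 and 0.0528), or either capsule day 28 array (0.0661 and 0.062). Neutrophil markers were lower in 6 of 11 members (8 list alone), with S100a8 at -1.74 and Mmp8 at least 1.81-fold lower. The median was -1.11, or -0.78 with bounds (adjusted p 0.00108, 0.327 estimated). Cell cycle genes were lower in 10 of 14 and higher in 1 (same list alone), with Top2a and Aurka at -1.30 and Pcna at -1.18. The median was -0.72 (adjusted p 0.00191, 0.327 estimated).

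Oxidative phosphorylation genes were lower at capsule day 28 than at day 7 in 8 of 15 members (8 list alone), with Atp5a1 at -1.50, Cox7b at -1.45 and Ndufa4 at -1.36; a second probe of Atp5a1 gave 0.00 (adjusted p 0.993). The median was -0.61 (adjusted p 0.00287, 0.327 estimated). MHC class II genes were higher in 5 of 11 (5 list alone), with H2-Oa at 1.49, H2-Eb1 at 1.17 and Cd86 at 1.15. The median was 0.55 (adjusted p 0.00971, 0.327 estimated), or 0.35 without capsule day 7 replicate 2. Resident macrophage genes were higher in 6 of 15 and lower in 1, Fn1 at -0.92 (7 and 1 list alone), with Vsig4 at 2.31, and the list failed without capsule day 28 replicate 2 (0.128) or with a detection p of 0.01 (0.0638). The median was 0.60 (adjusted p 0.0431, 0.465 estimated), or 0.91 without capsule day 28 replicate 1. The matrix (0.38), inflammatory (0.72), giant cell (0.0813), mesothelial (0.126), dissociation stress (0.21) and T and NK cell lists (0.0512) did not pass, nor did the complement and eosinophil and mast cell lists, whose median, mean and test differed in sign. The other probes of Tgfb2 and Adcy4 did not pass (adjusted p 0.353 and 0.0584), nor did 1 of 2 of Cdkn2a (0.714), the remaining one of which gave 3.62. With median scaling the median of all genes moved to -0.14 and 35.7% of the changed genes were higher, against 51.9% here. Without capsule day 7 replicate 2 the count was 2230 and without capsule day 28 replicate 2 it was 2078.

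Already at capsule day 14, 2610 genes differed from day 7, 1292 higher and 1318 lower. Clec4g was at least 82.8-fold higher, Tgfb2 rose by 3.61 (SE 0.52, adjusted p 0.000257) and Adcy4 by 3.48. Psmc1 was at least 14.6-fold higher (adjusted p 0.0132) but failed without either capsule day 7 array (0.0623 and 0.0568), or either capsule day 14 array (0.0608 and 0.0551). Eif2s3y was at least 34.0-fold lower, and Csta2 (-4.26) and Rsl1d1 (-3.65, adjusted p 0.021), each detected on 1 of 2 day 14 arrays, and Evl (-3.31) fell. Rsl1d1 failed without either capsule day 7 array (0.0816 and 0.0852), with the authors' values (0.0555) or with the compared arrays alone (0.158), and its change was -0.93 without capsule day 14 replicate 1 and -6.38 without replicate 2. Of the resident macrophage genes 10 of 15 were higher (13 list alone). The median was 1.05 (adjusted p 4.23e-05, 0.448 estimated). Neutrophil markers were lower in 6 of 11 (7 list alone). The median was -0.97, or -0.86 with bounds (adjusted p 0.0131, 0.448 estimated). Dissociation stress genes were higher in 4 of 14 and lower in 1 (7 and 1 list alone), and the list failed without capsule day 7 replicate 2 (0.0824) or capsule day 14 replicate 1 (0.0601), with the authors' values (0.0704) or the slide as a random block (0.0621). The median was 0.47 (adjusted p 0.0361, 0.448 estimated). Signs of median, mean and test differed for interferon, scavenger, complement, glycolysis, dendritic, eosinophil and mast cell and endothelial lists, none of which passed. With median scaling 36.3% of the changed genes were higher, against 49.5% here. The count was 1679 without capsule day 7 replicate 2 and 1513 without capsule day 14 replicate 2.

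At capsule day 21, 3815 genes differed from day 7, 2003 higher and 1812 lower. Clec4g was at least 80.1-fold, Psmc1 at least 19.2-fold and Sprr2e at least 11.5-fold higher, and Plat, the tissue plasminogen activator gene, rose by 4.05 (1 of 2 day 7 arrays). Csta2 was at least 44.8-fold lower, Eno2 changed by -3.9997 and Wfdc21 by -3.84 (-2.55 without capsule day 21 replicate 1); Chil1 was at least 30.9-fold lower but failed without capsule day 7 replicate 1 (0.0592). Cell cycle genes were lower in 10 of 14 and higher in 1 (11 and 1 list alone, median -0.67, adjusted p 0.00243, 0.277 estimated), oxidative phosphorylation genes lower in 8 of 15 (9 list alone, median -0.55, adjusted p 0.00638, 0.277 estimated) and neutrophil markers lower in 5 of 11 (6 list alone, median -0.77, adjusted p 0.00638, 0.294 estimated). The cell cycle median was -0.36 without capsule day 21 replicate 1 and -1.01 without replicate 2. Giant cell and osteoclast genes were lower in 6 of 12 and higher in 1 (7 and 3 list alone), but from the members detected on all arrays the median was 0.17 and the list did not pass (adjusted p 0.988), nor with the authors' values (0.0824). Over all 12 members the median was -0.997 (adjusted p 0.0212, 0.277 estimated). Resident macrophage genes were higher in 9 of 15 and lower in 1 (11 and 1 list alone, median 0.94, adjusted p 0.00412, 0.349 estimated), class II genes in 6 of 11 (6 list alone, median 0.55, adjusted p 0.00954, 0.277 estimated) and inflammatory cytokine genes in 7 of 12, with 1 lower (same list alone, median 0.86, adjusted p 0.0113, 0.304 estimated). T and NK cell markers were higher in 3 of 8, and the list failed without capsule day 21 replicate 2 (0.0711). The median was 0.78, or 1.39 without capsule day 21 replicate 1, or 0.52 with bounds (adjusted p 0.0212, 0.294 estimated). Mesothelial markers were higher in 4 of 7, and the list failed without capsule day 7 replicate 2 (0.0859) or with the authors' values (0.0641). The median was 0.85, or 0.49 with bounds (adjusted p 0.0328, 0.277 estimated). The complement list, which failed, differed in sign between median, mean and test. With median scaling the median of all genes moved to -0.14 and 36.9% of the changed genes were higher, against 52.5% here.

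Capsule day 28 was compared with day 21 on slide 4, which held both groups, and 101 genes changed, 27 higher and 74 lower. This count was 1 with the compared arrays alone, 48 with the authors' values and 161 without background correction. With the compared arrays alone none of the 8 genes named next passed (adjusted p 0.0774 to 0.228), and with the authors' values Rragd (0.116), Hspb7 (0.134) and Rhov (0.0604) did not. The endothelial adhesion gene Sele changed by -2.64 (SE 0.21, adjusted p 5.41e-05), the growth factor gene Csf2 by -2.61, Clec4g by -2.51 and Mall by -2.44. Fam171b rose by 1.40 (adjusted p 0.00121; 1 of 2 day 21 arrays), Rragd by 1.53 and Hspb7 by 1.51, and Rhov was at least 2.28-fold higher. Inflammatory cytokine and enzyme genes were lower in 2 of 12 members (9 lower and 1 higher list alone), with Tnf at -1.46. The median was -0.79 (adjusted p 8.62e-07, 0.171 estimated). Matrix genes were lower as a list although 0 of 9 members passed on their own (5 list alone). The median was -0.54, or -0.40 with bounds (adjusted p 0.000133, 0.171 estimated). The interferon, oxidative phosphorylation, B cell and dendritic lists, which failed, differed in sign between median, mean and test. The count fell to 15 without capsule day 21 replicate 2, 56 without capsule day 28 replicate 1 and 52 without capsule day 28 replicate 2. Rragd failed without capsule day 21 replicate 2 (0.119) or capsule day 28 replicate 1 (0.113). Hspb7 failed without capsule day 21 replicate 2 (0.99, adjusted p 0.0926), or either capsule day 28 array (0.0725 and 0.0786). Rhov failed without either capsule day 21 array (0.0773 and 0.0926) or capsule day 28 replicate 1 (0.152).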

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

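All 5 explanations weighed here were chosen after the results they bear on had been seen. The interaction test itself was set before the data were examined.

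The difference between capsule and lavage cells changed between day 7 and day 14 for 1241 genes by an interaction test. The largest named changes toward capsule were Psmc1 (5.87), Ccl12 (4.44), Gas6 (3.28) and Cpa3 (3.16), and those toward lavage were Eif2s3y (-5.87), Fzd1 (-4.19), Zfp661 (-3.04) and Glul (-2.97). The lists that passed were cell cycle (median 1.48), eosinophil and mast cell marker (1.22), MHC class II (0.74), matrix (0.71) and dissociation stress (0.63). None of these passed with an estimated correlation (adjusted p 0.0674 to 0.623). Class II, matrix and dissociation stress did not pass without some single arrays, as given above. Psmc1, not detected on capsule day 7 arrays, did not pass without any 1 of the capsule arrays (0.0815 to 0.0858), without replicate 1 of lavage day 7 (3.63, 0.127) or day 14 (0.127), with the authors' values (0.0971) or without a detection filter (0.0715). The same 3 lists did not pass with median scaling (0.107 to 0.387) or the compared arrays alone (0.0548 to 0.0552), class II and dissociation stress with genes detected on all arrays (0.0587 each), and matrix and dissociation stress with the authors' values (0.0566 and 0.107). Dissociation stress did not pass with the slide as a random block (0.0683), nor matrix with a detection p of 0.01 (0.07) or without a detection filter, where its median was 0.036 (0.547). Eif2s3y is Y-linked, the labels do not state the sex of the pooled mice, and Ccl12 was at background on lavage day 14 arrays. For Cpa3 the capsule arrays of both days lay at background, so its value follows its fall in lavage cells. The cell cycle list was higher in lavage day 7 against day 0. It passed neither in lavage day 14 against day 0 nor in capsule day 14 against day 7. Capsule day 14 was on its own slide, so for this test a slide effect and a change over time cannot be told apart.

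The first pattern weighed was the higher level of cytokine, chemokine and immediate early genes in capsule cells at both days. More neutrophils in capsule cells would raise all their abundant transcripts. The neutrophil list median was 0.23 at day 7 and -0.046 at day 14, and S100a9 differed by 0.64 (arrays overlapping) and -0.63. This argues only against a larger share of them. Collagenase digestion may have raised these genes. The dissociation stress list (median 2.42 at day 7, 2.97 at day 14) cannot decide this. It holds genes of the pattern, such as Fosb, and was also higher in undigested lavage cells at day 2 (0.83 against day 0). Activation before digestion, which no array here separates from it, and the biological difference of the places stay open, untested.

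The second pattern was the change of 3398 genes between capsule day 7 and day 28, whose arrays lay on different slides with different numbers of detected probes. If dim probes read as detected on slides 3 and 4 alone were the whole cause, calls would be at least 1.5 times as frequent among genes not detected on all 18 arrays; 34.6% of these and 30.1% of the genes detected on all were called, which argues against that as the whole cause. A shift of single probes between slides stays open, because no group lay on both pairs of slides; with the slide as a random block 3514 genes changed, but that fit cannot part the pairs either. A change over time may therefore account for these genes, as may the slides, and the time itself was not tested apart from them.

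The third pattern was that some resident macrophage genes had returned near their day 0 level at lavage day 14 while others had not. Dilution of resident cells by cells lacking these transcripts would lower the members alike. The SD of their changes was 2.02 against a median standard error of 0.29, with 2 members higher and 5 lower. This unevenness defined the pattern, so it cannot decide on dilution. Dilution and another state of the cells stay open, untested.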

How the results depend on the processing

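The restriction to genes detected on all arrays and the fit of slides 1 and 2 without the block were added after the data had been seen; the other alternatives were set before. The comparisons are given below in 1 order: lavage day 2, 4, 7 and 14 against day 0, lavage day 14 against day 2, capsule day 14, 21 and 28 against day 7, capsule day 28 against day 21, capsule against lavage at day 7 and at day 14, and the interaction. With each array left out in turn, changed genes numbered 1777 to 2334, 1933 to 2170, 2045 to 2334, 1296 to 1778, 1926 to 2428, 1513 to 2199, 2592 to 2847, 2078 to 2343, 15 to 83, 1701 to 1873, 2678 to 3339 and 768 to 1210. Where this left a group with 1 array, that array was assumed to vary like the other groups. Of 1108 such results for called genes 45 no longer passed, and of 432 for lists 37, all with their direction kept. With all probes as separate tests, which makes more tests, the counts were 4712, 5601, 5475, 3629, 4580, 4799, 6916, 5870, 233, 4314, 6945 and 2143. A change of at least 2-fold, a stricter demand, left 1125, 1169, 1267, 878, 1153, 988, 1311, 1136, 69, 1074, 1568 and 902. From the compared arrays alone, with fewer arrays to estimate the spread, 1868 genes changed in lavage day 14 against day 2, 1680 in capsule day 14 against day 7, 1 in capsule day 28 against day 21 and 821 in the interaction. Median scaling gave 3553 genes in lavage day 14 against day 0 and 4955 in lavage day 14 against day 2. The lavage day 14 arrays had the lowest mean intensity on slides 1 and 2 (585 and 689), but the cause of these counts was not tested. Capsule day 28 against day 21 gave 161 genes without background correction and 48 with the authors' values, for which the cause was not tested, and 30 of fewer genes tested when only those detected on all arrays were used. The other counts under these alternatives, a mean-dependent prior, no detection filter, a detection p of 0.01, an offset of 50 and both slide blocks lay within 1.5 times those reported. Reversed values came from 1 other probe each of Gpnmb (-0.015) and Lama3 (0.44) in lavage day 2 against day 0, Lama3 (0.18) in day 4 against day 0, Atp5a1 in capsule day 28 against day 7 (0.0037) and in capsule against lavage at day 14 (0.017), and Cldn10 in capsule against lavage at day 7 (0.0083); the cause was not tested. The giant cell list in capsule day 21 against day 7 reversed to 0.17 when only its members detected on all arrays were used. Every other result for a named gene or list kept its direction under the alternatives it was tried with. Of 106 other-probe results 30 no longer passed, the reversed ones included. Irf7, not called in lavage day 14 against day 0, passed there with an offset of 50, no background correction, median scaling, genes detected on all arrays, the compared arrays alone and a mean-dependent prior. Named genes no longer passed in 15 of 269 results with the compared arrays alone, 8 with the authors' values, 2 with median scaling and 1 without a detection filter. List results no longer passed in 82 of 103 with an estimated correlation, 14 with median scaling, 9 with the authors' values, 6 with the slide as a random block, 5 with a detection p of 0.01, and 4 each with the compared arrays alone, no background correction, no detection filter and an offset of 50. The random block also came with a different list test, so its 6 losses cannot be laid to the slide. Of the 77 lists with enough genes detected on all arrays, 12 no longer passed, the reversed one included. The replicate block ended 2 of 163 named gene calls (Ndufa1 and H2-DMb1) and 6 of 66 list calls and changed no other; the same 12 arrays without the block ended 1 of these gene calls and 5 of these list calls, so most of the losses came with the smaller number of arrays. Signal over background limits dim genes: values of genes not detected in a group are bounds, the detected probes differed between slides, and 28 probes lay near the top of the scale.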

Other observations

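The observations below were chosen after the values had been seen, and no test beyond those of the comparisons was set for them.

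Smooth muscle and myofibroblast genes, of interest because myeloid cells have been proposed as a source of capsule myofibroblasts, did not pass as a list in any of the 12 comparisons. Acta2, the smooth muscle actin gene, was at 7.22 in lavage cells at day 0, 9.31 at day 2 and 6.23 at day 14, and in capsule cells at 7.52 at day 7 and 5.38 at day 28, when 1 of 2 arrays detected it. It changed by 2.09 in lavage day 2 against day 0 and by -2.14 in capsule day 28 against day 7.

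Rnase2a stayed between 15.38 and 15.52 in lavage and capsule cells from day 7 on, high on the scale, where differences may be compressed. Lyve1 went from 10.89 at lavage day 0 to 14.21 at lavage day 7 and lay between 13.74 and 14.28 in capsule cells. Ccl8 went from 5.60 at lavage day 0 (1 of 2 arrays) to 11.78 at lavage day 7 and 9.71 at day 14, and lay between 12.997 and 13.87 in capsule cells.

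Sex chromosome transcripts varied by group, so comparisons, as with day 0, may carry a sex difference (not tested). Eif2s3y was not detected at lavage day 0 and 2 or capsule day 14, was detected on 1 of 2 arrays at lavage day 4, and lay at 9.35 to 10.57 elsewhere. Kdm5d was not detected at lavage day 0 and lay at 6.47 to 8.64 elsewhere, capsule day 14 included. Xist was detected on all arrays, at 8.35 to 10.98. The haemoglobin genes Hba-a1 and Hbb-bt were at 10.87 and 11.57 at lavage day 0 and at 11.90 and 12.62 at lavage day 4, and at most at 6.66 and 7.30 elsewhere. On slides 3 and 4, 313 probes were detected on all arrays there and on none of slides 1 and 2, and 25 probes showed the reverse.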
